A study of Sus scrofa domesticus with 58 samples.

How the data were processed

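Gene expression was measured by 3' mRNA sequencing in jejunum and colon of 30 male pigs, and 58 libraries were deposited, 28 of jejunum and 30 of colon. Per the labels' protocols, total RNA was taken from frozen tissue with a column kit and turned into libraries that read the 3' end of polyadenylated transcripts, so read counts do not scale with transcript length. Per the submitters' processing notes, FastQC, TopHat, HTSeq and DESeq2 were used with the pig genome build Sscrofa11.1, with versions, settings and annotation release not given in the sources used here.

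The authors deposited 6 tables, each holding the comparison of 1 pair of groups within a tissue. Per the file headers, each table gives a normalised read count signal per library, a mean over libraries, a log2 fold change with its standard error, a p-value and an adjusted p-value, all computed by the authors with DESeq2. The deposited signal is a count of reads per gene divided by a size factor per library, set by the authors over the libraries of that table. The steps between the values of a library gave back its size factor and its whole reads, with 100% of values whole at a tolerance of 0.01. Tables that shared a library gave the same reads for it. All per-sample columns were mapped to a labelled library, with 0 left over.

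Of 35670 gene IDs in the tables, 15623 matched a symbol in the reference list of gene names, and genes without a symbol were counted but not named. Chromosomes and coordinates came from a RefSeq gene table of the same build, matched by symbol. Total reads per library ran from 2296661 to 6840582, and a median of 18.1% of the reads fell on genes without a symbol. No molecular identifiers were recorded, so totals describe reads and not independent molecules. At these depths a gene with a mean of 10 normalised reads carries a large counting error, and the tests below left out genes under that mean.

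Samples were grouped by tissue and diet as labelled, and animal numbers in the labels paired the tissues of 28 animals. The following choices were made before the data were examined: the comparisons, the tests, the threshold, the gene lists, the alternatives to be tried and the rule for naming genes. Each pair of diets within a tissue was compared inside its own table with limma 3.58.1 in R 4.3.3, with a variance trend, on log2 of the deposited value plus a pseudocount of 1. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The difference in response between tissues was tested on the jejunum minus colon difference of each animal, dosed against control. Jejunum and colon of the control animals were compared on log2 of CPM (a gene's reads scaled to a common library total) plus 1, with TMM factors from edgeR 4.0.16, over genes with a mean of at least 1 CPM.

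Altogether 32 gene lists (pathways, cell type markers and complexes) were tested in each comparison by camera with a preset correlation of 0.01, adjusted over the lists with at least 3 members measured. Camera asks whether the genes of a list differ between groups more than the other genes do. Camera with a correlation estimated from the data, and fry, which asks whether the genes of a list move on balance one way without reference to other genes, were run beside it. Counts described as adjusted over the list alone use a Benjamini-Hochberg adjustment over the members of a list only.

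Genes were named by a rule. For each diet comparison these were the 10 largest rises and the 10 largest falls past the threshold that had a symbol, or 5 each way between the doses. Where fewer than 10 passed, the genes with the smallest p up to 10 were added and said not to have passed. For each list that passed, the 4 members with the smallest p were eligible. For the tissue comparison, the 10 largest each way past the threshold were eligible. No gene passed for the differences in response, so the 10 with the smallest p were eligible there. VDR, CYP24A1, CYP27B1, TRPV6, S100G and ATP2B1 were given wherever they were measured. Some genes that the rule allows are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

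The limma fits, and camera with the preset correlation in the diet comparisons, were first tested on simulated data. These were drawn from the means, spreads and depths of the real libraries with a known set of genes changed 1.5, 2 or 4 fold. Genes were drawn independently, so correlation within a list was not simulated, and the other tests and settings were not tested in this way. Other settings that were tried are the pseudocount (0.5 and 5), the filter on low values (none, and a mean of at least 50), TMM rescaling, edgeR quasi-likelihood and DESeq2 1.42.0 on the recovered reads, and the adjusted p of the authors' table. Further settings were array weights, all 3 diets in a single fit, a smooth muscle score as a covariate, and leaving out the smallest library of each group. For the tissues they were an animal block, no TMM factors, a pseudocount of 0.1 and no filter. Further settings were chosen after seeing the data. These were a library set term, leaving out the libraries of set 3, keeping the libraries of a single set, and a position score as a covariate. For the tissues they were fits of all 3 diets with dose, or with dose and library set, as terms.

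Library sets were inferred from the values, since the labels record no batch. A score of 3 genes, SMARCD2, MIF4GD and SASH3, whose values fell into separate ranges, was split at 3. Transcripts of 17 hepatocyte plasma proteins were averaged, and this score was split at 7.5. The position score was the mean log2 CPM of 4 genes of the proximal small intestine (GATA4, ONECUT2, GIP and RBP2) minus that of 3 distal genes, HOXC8 and HOXC9 among them. For every count of genes, 100 splits of the same libraries into groups of the same sizes were drawn with a fixed seed, the real split included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.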

Results

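Messenger RNA was measured in 58 intestinal libraries from 30 male fattening pigs (Large White by Landrace), fed 1 of 3 diets that differed in added vitamin D. The control diet is labelled without a dose, and the other diets held 5000 or 10000 IU of cholecalciferol per kg of feed. Jejunum was sequenced from 10 control animals, 9 on 5000 IU and 9 on 10000 IU, and colon from 10 animals of each diet, with both tissues from 28 animals. Total reads per jejunum library ran from 2637334 to 6318399 in controls, from 2296661 to 6045882 at 5000 IU and from 2666023 to 4635481 at 10000 IU. In colon they ran from 3791580 to 6467827 in controls, from 3625681 to 6840582 at 5000 IU and from 3159139 to 5924758 at 10000 IU. Reads were found for 30109 of the 35670 gene IDs in at least 1 library. Mitochondrially encoded transcripts took a median of 18.9, 17.4 and 19.02% of jejunum reads and 16.2, 12.5 and 16.1% of colon reads in control, 5000 IU and 10000 IU animals. Gene values below are normalised reads, as mean ± SD over the n libraries of a group, and coordinates are on build Sscrofa11.1.

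Transcripts of plasma proteins that hepatocytes secrete differed between libraries of the same diet. Albumin (ALB) lay between 7425 and 13543 CPM in 12 libraries, 9 of colon and 3 of jejunum, and between 148 and 3183 CPM in the other libraries. Transcripts of SMARCD2, MIF4GD and SASH3 split the remaining libraries again, with mean log2 CPM of 4.05 or more in 33 libraries and 2.12 or less elsewhere. These sets are not in the labels and are called set 1 (33 libraries, 25 of jejunum and 8 of colon), set 2 (13, all colon) and set 3 (the 12 with high ALB). Sets 1, 2 and 3 held 1, 6 and 3 of the control colon libraries, 2, 5 and 3 at 5000 IU, and 5, 2 and 3 at 10000 IU. In jejunum all 10 control libraries were in set 1, with 7 in set 1 and 2 in set 3 at 5000 IU, and 8 and 1 at 10000 IU. Library set as a term was a setting chosen after seeing the data. In the diet comparisons its value is given for the genes described in full, and for other named genes where it differed over 1.5 times from the pooled value.

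**Figure D1:**
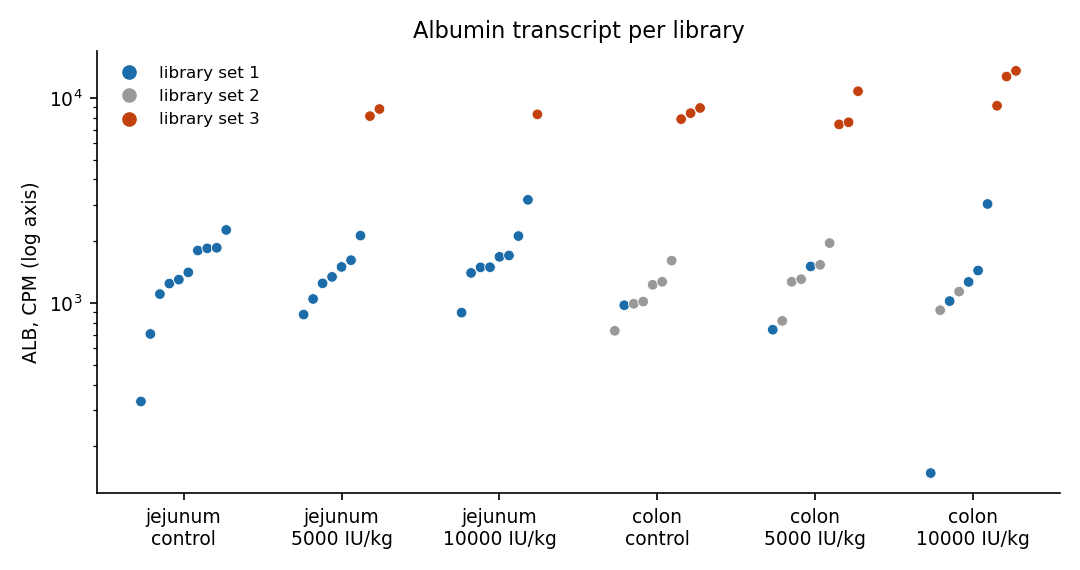
Albumin transcripts per library (CPM, log axis) by tissue and diet, with each point a library coloured by its set. The 12 libraries of set 3 sit between 7425 and 13543 CPM, above every other library.

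The comparison of 5000 IU with control in jejunum asks which genes of the small intestine respond to the lower added dose. OASL, an antiviral protein related to oligoadenylate synthetase (ENSSSCG00000009921, chromosome 14, 40900050 to 40917189), had 132 ± 171 normalised reads (n = 9) against 13.2 ± 13.6 (n = 10). All 9 dosed libraries were above the control median, with a log2 difference of 2.95 (SE 0.54, limma adjusted p = 0.20) and 2.81 with library set as a term. The peptide transporter TAP1 (ENSSSCG00000025618, chromosome 7, 25062772 to 25071989) had 1086 ± 304 against 671 ± 104, a log2 difference of 0.66, and 0.65 with library set as a term. RSAD2, an antiviral enzyme, had 116 ± 66.5 against 44.2 ± 28.1, and OAS2, which makes the activator of RNase L, 295 ± 268 against 84.9 ± 40.7. Of 46 interferon response genes 44 were higher, with a median log2 difference of 0.49 (camera adjusted p = 1.2e-22; adjusted p = 0.17 with an estimated correlation), and 15 passed when adjusted over the list alone. A library set term left 46 of 46 higher, with a median of 0.51.

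Genes of bile acid transport and its control were examined in the same animals. SLC51A, a subunit of the basolateral bile acid exporter (ENSSSCG00000011846, chromosome 13, 133851775 to 133869753), had 375 ± 225 normalised reads against 154 ± 84.7, a log2 difference of 1.21 and 1.32 with library set as a term. The bile acid receptor FXR (NR1H4) had 109 ± 91.6 against 37.1 ± 23.6, and the ileal bile acid uptake carrier SLC10A2 had 85.3 ± 104 against 5.70 ± 9.66. The log2 difference of SLC10A2 was 2.72, and 3.88 with library set as a term and 1.79 with a position score as a covariate. Of 10 genes of the bile acid and FXR pathway 9 were higher, with a median log2 difference of 0.70 (camera adjusted p = 9.7e-07; adjusted p = 0.0012 with an estimated correlation; fry adjusted p = 0.0048). SLC51A, NR1H4 and SLC10A2 passed when adjusted over the list alone. A library set term left 8 of 10 higher, with a median of 0.48. The position score, made from 7 marker genes of the small intestine, left 10 of 10 higher as a covariate, with a median of 0.88.

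LYPD8, which keeps flagellated bacteria off the epithelium (ENSSSCG00000013973, chromosome 2, 52447149 to 52458070), had 1876 ± 1005 normalised reads against 710 ± 363, with all 9 dosed libraries above the control median. Its log2 difference was 1.40 (SE 0.30, adjusted p = 0.77) and 1.17 with library set as a term. FGFBP1, a carrier of fibroblast growth factors, had 29.96 ± 16.7 against 7.63 ± 6.69, and SLC44A4, a thiamine pyrophosphate carrier, 891 ± 410 against 423 ± 157. Cholesterol synthesis genes were higher in 21 of 23 cases (median 0.40, adjusted p = 4.4e-08; adjusted p = 0.27 with an estimated correlation), and CYP51A1, a sterol demethylase, had 583 ± 190 against 391 ± 117. Adipocyte and lipid genes such as SCD, a fatty acid desaturase with 382 ± 240 against 153 ± 80.4, and LPL, a lipase with 217 ± 108 against 127 ± 52.0, gave a median of 0.28 (adjusted p = 0.033; adjusted p = 0.27 with an estimated correlation, and 0.17 for the preset one with library set as a term). Unfolded protein response genes, among them the chaperone CALR (0.64, and 0.26 with library set as a term), were higher in 18 of 21 cases (adjusted p = 0.0039; adjusted p = 0.77 with an estimated correlation, and 0.17 for the preset one with library set as a term). Goblet cell and mucus genes (10 of 13 higher, median 0.33, adjusted p = 0.0081), inflammatory genes such as SOCS1 (13 of 19 higher, adjusted p = 0.027) and stem cell and proliferation genes (21 of 25 higher, median 0.15, adjusted p = 0.033) passed too. With an estimated correlation their adjusted p were 0.27, 0.36 and 0.83.

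Of 12984 genes tested in this comparison limma passed 0, with 511 at an unadjusted p under 0.05 where 649 were due by chance. The number under 0.05 was 289 with library set as a term and 1110 with the position score. On the same reads edgeR passed 0 (684 at p under 0.05) and DESeq2 passed 4, which were OASL, LYPD8 and 2 genes without a symbol. The authors' table passes 7, all higher, adding OAS2, TAP1 and KRT7, a keratin of simple epithelia outside the naming rule and chosen after its values were seen. KRT7 gave 1.35, and 0.68 with library set as a term.

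The comparison of 10000 IU with control in jejunum asks the same at the higher dose. OASL had 117 ± 93.9 normalised reads (n = 9) against 12.5 ± 12.9 (n = 10), with all 9 dosed libraries above the control median and a log2 difference of 2.87 (SE 0.60, adjusted p = 0.88), 2.70 with library set as a term. OAS2 had 233 ± 156 against 80.8 ± 38.5, and 39 of 46 interferon response genes were higher (median 0.43, adjusted p = 3.6e-09; adjusted p = 0.41 with an estimated correlation). CLDN2, a claudin that forms cation and water pores (ENSSSCG00000037234, chromosome X, 87352695 to 87355724), had 175 ± 104 against 73.1 ± 23.3, all 9 above the control median, with a log2 difference of 1.10 and 0.94 with library set as a term. All 10 bile acid genes were higher (median 0.65, adjusted p = 2.5e-04; adjusted p = 0.18 with an estimated correlation), with NR1H4 at 59.7 ± 30.4 against 35.5 ± 22.8 and SLC10A2 at 58.3 ± 82.5 against 5.45 ± 9.27. Cholesterol synthesis genes were higher in 21 of 23 cases (median 0.33, adjusted p = 6.3e-07; adjusted p = 0.41 with an estimated correlation), with MVD at 95.3 ± 24.2 against 65.3 ± 18.2 and SQLE at 282 ± 123 against 178 ± 66.1.

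At 10000 IU in jejunum T and NK cell markers were lower in 28 of 31 cases (median -0.48, adjusted p = 3.6e-09; adjusted p = 0.31 with an estimated correlation). Among them IL2RB, a receptor chain for interleukins of lymphocyte growth, had 143 ± 40.4 against 210 ± 76.5, and CD247, the signalling chain of the T cell receptor, 235 ± 59.0 against 335 ± 118. Macrophage and myeloid markers were lower in 17 of 21 cases (median -0.58, adjusted p = 2.4e-06; adjusted p = 0.41 with an estimated correlation). Among these XCR1, a receptor of cross-presenting dendritic cells, had 30.96 ± 8.36 against 54.3 ± 16.7, with 0 of 9 dosed libraries above the control median, and CD68, a lysosomal protein of macrophages, had 102 ± 62.4 against 185 ± 115. MHC class II genes (6 of 7 lower, median -0.49, adjusted p = 0.0072) and B and plasma cell markers (18 of 22 lower, median -0.48, adjusted p = 0.042) were lower too, with adjusted p of 0.45 and 0.70 with an estimated correlation. Outside these lists, NFATC2, a transcription factor of activated T cells, had 39.9 ± 19.05 against 70.8 ± 21.5, and DNASE1L3, a nuclease of dendritic cells, 91.4 ± 80.99 against 231 ± 123.

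MMP2, a gelatinase of connective tissue (ENSSSCG00000002829, chromosome 6, 30059247 to 30087031), had 38.2 ± 25.2 against 76.6 ± 29.8, a log2 difference of -1.10 and -1.15 with library set as a term. Extracellular matrix genes, SPARC among them with 510 ± 227 against 856 ± 367, were lower in 22 of 28 cases (median -0.23, adjusted p = 0.0072; adjusted p = 0.64 with an estimated correlation). CCNG1, a p53 target of the cell cycle, had 191 ± 33.5 against 285 ± 53.4, with 0 of 9 dosed libraries above the control median. Ribosomal proteins such as RPL7 and RPS27A were lower in 32 of 35 cases (median -0.18, adjusted p = 2.6e-06; adjusted p = 0.45 with an estimated correlation), and nuclear respiratory chain subunits in 30 of 36 (median -0.12, adjusted p = 0.0072; adjusted p = 0.70 with an estimated correlation). Fatty acid oxidation genes were lower in 14 of 22 cases (median -0.18, adjusted p = 0.023; adjusted p = 0.41 with an estimated correlation), with CPT1A, which carries fatty acids into mitochondria, at 184 ± 123 against 341 ± 260 and PLIN2, a lipid droplet coat, at 174 ± 107 against 326 ± 161. Smooth muscle markers were higher in 21 of 24 cases (median 0.26, adjusted p = 0.023), erythroid markers in 3 of 3 (median 0.90, adjusted p = 0.032) and vitamin D receptor target genes in 17 of 27 (median 0.20, adjusted p = 0.038). Immediate early and heat shock genes were lower in 20 of 25 cases (adjusted p = 0.015). Their adjusted p with an estimated correlation were 0.70, 0.31, 0.41 and 0.49. The receptor target and immediate early lists ended at 0.13 and 0.090 with library set as a term.

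Of 12933 genes tested here limma passed 0, with 664 at an unadjusted p under 0.05 where 647 were due by chance, and edgeR passed 0 (807). With the set term and with the position score 592 and 746 genes were under 0.05. DESeq2 and the authors' table passed 1, OASL.

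Between the doses in jejunum (9 libraries each), FGL2, a fibrinogen-like product of T cells and macrophages (ENSSSCG00000015413, chromosome 9, 102869044 to 102875564), had 337 ± 67.5 normalised reads at 10000 IU against 561 ± 176 at 5000 IU. None of the higher-dose libraries was above the median of the lower dose, and the log2 difference was -0.70 (SE 0.18, adjusted p = 0.9998), -0.75 with library set as a term. The hormone SST had 259 ± 85.3 against 160 ± 50.02, in a list of enteroendocrine and tuft cell genes with 12 of 14 higher (median 0.45, adjusted p = 0.0070; adjusted p = 0.63 with an estimated correlation). Myeloid markers were lower at 10000 IU in 19 of 21 cases (median -0.60, adjusted p = 1.3e-06; adjusted p = 0.63 with an estimated correlation), with the complement chain C1QB at 120 ± 84.3 against 257 ± 213 and the complement receptor VSIG4 at 15.1 ± 10.2 against 26.8 ± 10.3. Extracellular matrix genes were lower in 26 of 28 cases (median -0.30, adjusted p = 3.6e-05; adjusted p = 0.63 with an estimated correlation), with COL1A1 at 1822 ± 556 against 2708 ± 1141. All 36 nuclear respiratory chain subunits, COX5A among them, were lower (median -0.20, adjusted p = 3.5e-05; adjusted p = 0.80 with an estimated correlation). T and NK cell (26 of 30, adjusted p = 4.4e-04), interferon (35 of 46, median -0.16, adjusted p = 0.018), inflammatory (14 of 19, adjusted p = 0.019), endothelial (13 of 15, adjusted p = 0.020), immediate early (19 of 24, adjusted p = 0.015) and ribosomal genes (30 of 35, adjusted p = 0.039) were lower as well. In contrast 11 of 13 mitochondrially encoded transcripts were higher (median 0.22, adjusted p = 0.047). All of these ended at an adjusted p between 0.63 and 0.82 with an estimated correlation. With library set as a term the ribosomal and mitochondrially encoded lists ended at 0.11 and 0.18. Of 12959 genes limma passed 0, with 295 at an unadjusted p under 0.05, edgeR passed 0 (275), and DESeq2 and the authors' table passed 0 (697). With the set term and with the position score 316 and 891 genes were under 0.05.

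The comparison of 5000 IU with control in colon asks for the response of the large intestine. FCER1A, the IgE-binding chain of the receptor on mast cells (ENSSSCG00000006413, chromosome 4, 91118867 to 91125448), had 59.8 ± 38.7 normalised reads (n = 10) against 129 ± 34.5 (n = 10). Of the dosed libraries 1 was above the control median, with a log2 difference of -1.23 (SE 0.24, adjusted p = 0.35), -1.26 with library set as a term and -1.39 without the libraries of set 3. All 7 mast cell and eosinophil markers were lower (median -0.26, adjusted p = 0.0035; adjusted p = 0.18 with an estimated correlation), MS4A2, another chain of that receptor, at 176 ± 121 against 251 ± 119, and FCER1A passed when adjusted over the list alone. MEP1B, a brush border metalloprotease (ENSSSCG00000003732, chromosome 6, 116015021 to 116049796), had 7.32 ± 5.48 against 36.5 ± 23.1, with 0 of 10 dosed libraries above the control median and -1.96 with library set as a term. AOC1, the gut histamine-degrading enzyme, had 1133 ± 606 against 1977 ± 485.

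TK1, the thymidine kinase of S phase (ENSSSCG00000037120, chromosome 12, 3785997 to 3794824), had 146 ± 72.3 normalised reads against 61.2 ± 30.4 in colon at 5000 IU. All 10 dosed libraries were above the control median, with a log2 difference of 1.22 (SE 0.30, adjusted p = 0.71) and 1.21 with library set as a term. POLE, a replicative DNA polymerase, had 46.4 ± 23.1 against 19.6 ± 10.4, also with 10 of 10 above. Of 25 stem cell and proliferation genes 24 were higher (median 0.51, camera adjusted p = 3.1e-14; adjusted p = 0.18 with an estimated correlation), and 24 were with library set as a term (median 0.59). UBE2C, AURKB, MCM3 and NUSAP1 passed when adjusted over the list alone, as did MCM4 and HMGB2, which were chosen after their values were seen. AURKB, a kinase of chromosome segregation, had 144 ± 61.2 against 70.1 ± 27.9, and the replicative helicase subunit MCM3 had 137 ± 29.9 against 94.0 ± 25.2.

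Fatty acid oxidation genes were lower in colon at 5000 IU in 14 of 23 cases (median -0.25, adjusted p = 0.0035; adjusted p = 0.18 with an estimated correlation), and 4 passed when adjusted over the list alone. These were CPT1A with 470 ± 98.7 against 784 ± 269, CPT2 with 130 ± 26.6 against 189 ± 45.2, HADHB, a subunit of the trifunctional enzyme, with 384 ± 74.0 against 515 ± 108, and ANGPTL4, a PPAR target that inhibits lipoprotein lipase, with 78.9 ± 32.6 against 147 ± 60.7. FABP3, a fatty acid carrier, had 529 ± 201 against 255 ± 108. Mitochondrially encoded transcripts, COX1 and ND4 among them, were lower in 12 of 13 cases (median -0.40, adjusted p = 2.8e-04; adjusted p = 0.53 with an estimated correlation), and myeloid markers in 17 of 22, CD68 at 221 ± 99.4 against 352 ± 131 (median -0.18, adjusted p = 0.0035; adjusted p = 0.53 with an estimated correlation). Cholesterol synthesis genes, with LSS at 274 ± 148 against 139 ± 50.7, were higher in 20 of 23 cases (median 0.26, adjusted p = 6.1e-04; adjusted p = 0.53 with an estimated correlation). Goblet cell genes such as AGR2 (13 of 15 higher, adjusted p = 0.033), antimicrobial genes such as BPI (13 of 17, adjusted p = 0.045), inflammatory genes (18 of 22, adjusted p = 0.039) and smooth muscle markers (19 of 24, median 0.24, adjusted p = 0.013) were higher. Their adjusted p were 0.53, 0.58, 0.78 and 0.80 with an estimated correlation. The antimicrobial and inflammatory lists both ended at 0.11 with library set as a term. Without the libraries of set 3 the smooth muscle median was -0.12, with 9 of 24 higher.

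Of 13355 genes tested in this comparison limma passed 0, with 765 at an unadjusted p under 0.05 where 668 were due by chance, and edgeR passed 0 (725). The former number was 1359 with library set as a term and 618 without the libraries of set 3. DESeq2 and the authors' table passed 2, MEP1B and a gene without a symbol, both lower.

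The comparison of 10000 IU with control in colon asks for the response to the higher dose. EIF3M, a subunit of a translation initiation factor (ENSSSCG00000013315, chromosome 2, 28258399 to 28282812), had 50.4 ± 13.2 normalised reads (n = 10) against 96.5 ± 26.8 (n = 10), and RPL36AL, a ribosomal protein (ENSSSCG00000005006, chromosome 1, 179476638 to 179477820), had 960 ± 237 against 1538 ± 163. For both, 0 of 10 dosed libraries were above the control median. Their log2 differences were -0.92 and -0.72 (SE 0.19 and 0.16, adjusted p = 0.34 for both), and -0.81 and -0.65 with library set as a term. Ribosomal proteins were lower in 28 of 35 cases (median -0.22, adjusted p = 0.0015; adjusted p = 0.65 with an estimated correlation). RPL4 with 5699 ± 2723 against 10929 ± 4824, RPL5 with 7162 ± 2490 against 11986 ± 3257, and RPS24 with 3889 ± 1764 against 6552 ± 1874 passed when adjusted over the list alone. RPL4, RPL5 and RPS24 gave -0.59, -0.53 and -0.57 with library set as a term, where the pooled values were -0.99, -0.79 and -0.82. Without the libraries of set 3 the ribosomal list ended at 0.16.

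HADHB had 251 ± 98.8 normalised reads against 457 ± 101.03 in colon at 10000 IU, with 0 of 10 dosed libraries above the control median, a log2 difference of -0.96 and -0.77 with library set as a term. Fatty acid oxidation genes, CPT2 among them, were lower in 17 of 23 cases (median -0.36, adjusted p = 0.0051; adjusted p = 0.47 with an estimated correlation), with a median of -0.10 with library set as a term. Extracellular matrix genes were lower in 21 of 28 cases (median -0.24, adjusted p = 0.0051; adjusted p = 0.65 with an estimated correlation, and 0.066 for the preset one with library set as a term). The proteoglycan LUM had 295 ± 148 against 584 ± 237, the complement component C7 382 ± 160 against 795 ± 295, and the intermediate filament VIM 1438 ± 536 against 2379 ± 451. FCER1A had 64.2 ± 30.05 against 115 ± 31.2, with a log2 difference of -1.07, -1.21 with library set as a term and -0.73 without the libraries of set 3. Mast cell markers were lower in 6 of 7 cases (median -0.33, adjusted p = 0.032; adjusted p = 0.50 with an estimated correlation). Nuclear respiratory chain subunits (26 of 36 lower, adjusted p = 0.031), enteroendocrine genes (8 of 11, adjusted p = 0.032), smooth muscle markers (18 of 24, adjusted p = 0.032) and calcium, phosphate and magnesium transport genes (14 of 17, median -0.22, adjusted p = 0.039) were lower. They ended at 0.85, 0.50, 0.85 and 0.50 with an estimated correlation. The respiratory, smooth muscle and calcium lists ended at 0.28, 0.85 and 0.28 with library set as a term.

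Of 25 proliferation genes 20 were higher in colon at 10000 IU (median 0.31, adjusted p = 0.0022; adjusted p = 0.65 with an estimated correlation), with AURKB at 115 ± 52.5 against 62.2 ± 24.97 and CENPF at 459 ± 191 against 284 ± 120. Cholesterol synthesis genes were higher in 20 of 23 cases (median 0.20, adjusted p = 0.010; adjusted p = 0.65 with an estimated correlation) and in 23 of 23 with library set as a term (median 0.34). LSS, which closes the sterol ring, had 249 ± 117 against 123 ± 45.6, with 10 of 10 dosed libraries above the control median, and the sterol regulator SREBF2 had 755 ± 490 against 387 ± 333, a log2 difference of 0.96 that was 0.22 with library set as a term. Antimicrobial genes were higher in 14 of 18 cases (median 0.53, adjusted p = 0.0080; adjusted p = 0.50 with an estimated correlation), with LBP, which binds bacterial lipopolysaccharide, at 166 ± 128 against 78.8 ± 74.3 and PIGR, which carries IgA across the epithelium, at 18062 ± 5013 against 13438 ± 3527. Interferon genes (35 of 47, median 0.17, adjusted p = 0.032) and inflammatory genes (18 of 22, median 0.30, adjusted p = 0.032) were higher, with adjusted p of 0.85 and 0.65 with an estimated correlation.

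Of 13324 genes tested in this comparison limma passed 0, with 1341 at an unadjusted p under 0.05 where 666 were due by chance, 659 higher and 682 lower. The other tools passed 0 as well, edgeR with 1398 and DESeq2 and the authors' table with 2066 at p under 0.05. With library set as a term 809 genes had p under 0.05, and 1351 without the libraries of set 3. The latter setting leaves 5 dosed libraries of set 1 and 2 of set 2 against 1 and 6 controls. It therefore keeps the imbalance between sets 1 and 2.

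The doses were compared with each other in colon too (10 libraries each). GEM, a small GTPase (ENSSSCG00000006105, chromosome 4, 42458591 to 42471941), had 20.2 ± 16.5 normalised reads at 10000 IU against 55.1 ± 23.4 at 5000 IU, with a log2 difference of -1.60 (SE 0.40, adjusted p = 0.67) and -1.05 with library set as a term. S1PR3, a sphingosine phosphate receptor, had 55.6 ± 25.8 against 101.4 ± 33.1, and the endothelial cadherin CDH5 22.5 ± 11.2 against 45.4 ± 19.96, which gave -0.68 with library set as a term where the pooled value was -1.06. Smooth muscle markers were lower in 23 of 24 cases (median -0.52, adjusted p = 4.8e-06; adjusted p = 0.77 with an estimated correlation), with TPM2, a tropomyosin, at 1983 ± 1195 against 3313 ± 1570 (-0.76, and -0.43 with library set as a term). HMGB2, a chromatin protein of dividing cells, had 377 ± 124 against 766 ± 350, with 0 of 10 libraries above the median of the lower dose and -0.98 with library set as a term. Of the proliferation genes 22 of 25, CDK1 among them, were lower (median -0.20, adjusted p = 0.0014; adjusted p = 0.77 with an estimated correlation). Nuclear respiratory chain subunits (31 of 36 lower, adjusted p = 6.2e-05), extracellular matrix genes such as MFAP4 (24 of 29, adjusted p = 3.1e-04), B and plasma cell markers (15 of 20, adjusted p = 0.0066), endothelial markers such as EMCN (12 of 16, adjusted p = 0.011; EMCN itself -0.71, and -0.40 with library set as a term), enteroendocrine genes such as CHGB (8 of 10, adjusted p = 0.016) and ribosomal proteins (29 of 35, adjusted p = 0.024) were lower. All 13 mitochondrially encoded transcripts were higher (median 0.38, adjusted p = 0.0035). These ended at adjusted p between 0.77 and 0.98 with an estimated correlation, and the ribosomal list at 0.054 with library set as a term. Of 13376 genes limma passed 0, with 1000 at an unadjusted p under 0.05 where 669 were due by chance, and edgeR (800), DESeq2 and the authors' table (1557) passed 0 too. The limma number was 665 with library set as a term, 624 without the libraries of set 3 and 540 with a smooth muscle score as a covariate.

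**Figure D2:**
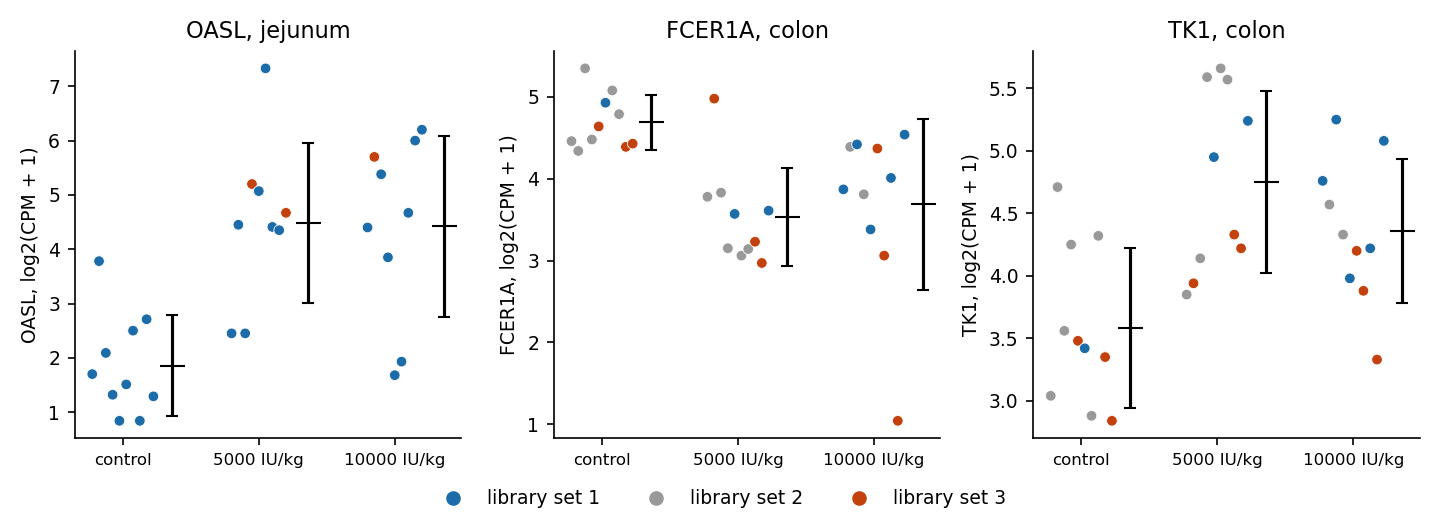
OASL in jejunum and FCER1A and TK1 in colon as log2(CPM + 1) per library by diet, with points coloured by library set and bars giving mean ± SD. All 9 jejunum libraries at each dose are above the control median for OASL, and 1 of 10 colon libraries at 5000 IU is above it for FCER1A.

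**Figure D3:**
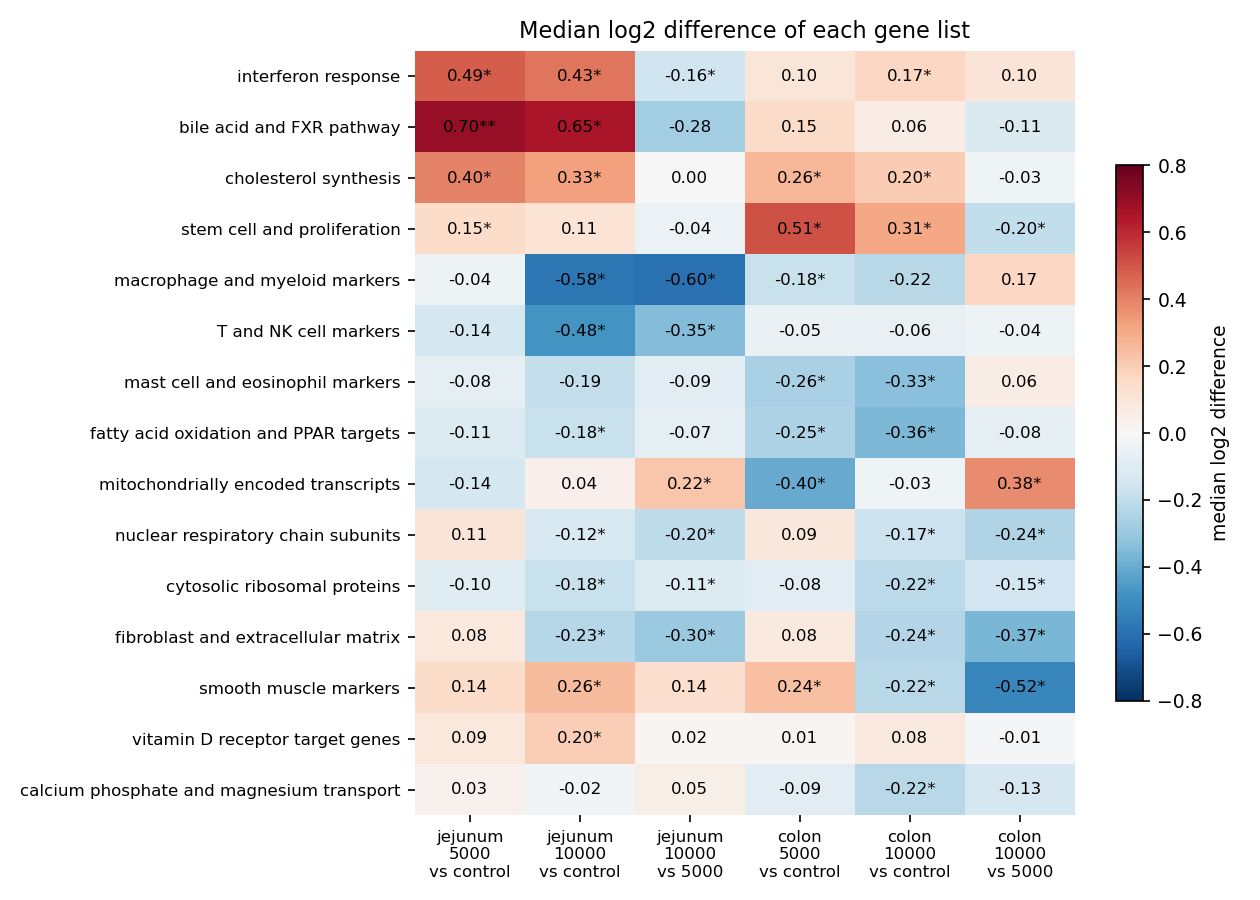
Median log2 difference of the gene lists named at left (vertical axis) in each diet comparison (horizontal axis), with 1 star for a camera adjusted p under 0.05 and a double star where it also held with an estimated correlation. Interferon response and bile acid genes are higher in jejunum at both doses, and the double star stands at bile acid genes in jejunum at 5000 IU.

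The doses were also compared in their direction over all genes, with the same control animals in both. In jejunum 67.0% of 12779 genes moved the same way at both doses (r = 0.575 across genes, which are not independent replicates), where sharing the controls alone gave a median of 65.2% and r = 0.480 in simulations without a dose effect. With separate control animals for each dose the median r was 0.169. In colon r was 0.452 over 13121 genes, against a median of 0.574 in such simulations and 0.106 with separate controls. The simulated r ran from 0.080 to 0.786 in jejunum and from 0.101 to 0.857 in colon. Both observed values lie within the range that sharing the controls alone gave. No gene passed at both doses in either tissue, with 0 limma calls at each dose.

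Whether jejunum and colon respond differently was tested on the jejunum minus colon difference of each animal (9 dosed against 10 control animals at each dose). The tables of the tissues were normalised separately, so only dosed minus control values are given, and not levels between tissues. At 5000 IU the jejunum minus colon difference of SLC51A was 1.19 log2 units higher in dosed animals than in controls (SE 0.38, adjusted p = 0.998). For this, 9 of 9 dosed animals were above the control median, and the value was 1.26 with library set terms. All 8 bile acid genes measured in both tissues differed that way (median 0.94, adjusted p = 6.2e-04; adjusted p = 0.11 with an estimated correlation). The antiviral genes IFIT1 and RSAD2 differed by 1.56 and 1.46, and 41 of 46 interferon genes differed upward (median 0.33, adjusted p = 8.1e-06; adjusted p = 0.78 with an estimated correlation). HMGB2 differed by -1.34 and 23 of 25 proliferation genes downward (median -0.28, adjusted p = 6.2e-04; adjusted p = 0.78 with an estimated correlation). SCD differed by 1.07 (0.71 with library set terms), XKR8, a scramblase of apoptotic membranes, by -1.81 and the growth factor EREG by 1.91.

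At 10000 IU the lysosomal protease CTSZ (ENSSSCG00000007522, chromosome 17, 59141497 to 59149377) differed in this way by -1.65 (SE 0.41, adjusted p = 0.90), and by -1.11 with library set terms. ABHD5, the activator of adipose lipase, differed by 0.90 and OASL by 2.06, 1.80 with library set terms. Interferon genes (30 of 46 upward, median 0.21), calcium, phosphate and magnesium transport genes such as CLDN2 (15 of 16 upward, median 0.35) and smooth muscle markers (20 of 24 upward, median 0.42) differed at an adjusted p of 0.014, and myeloid markers such as LAPTM5 (16 of 21 downward, median -0.60) and MHC class II genes (7 of 7 downward, median -0.47) at the same value. With an estimated correlation their adjusted p were 0.90, 0.23, 0.90, 0.90 and 0.82, and with library set terms the smooth muscle list ended at 0.41. Of 12389 and 12366 genes limma passed 0 at 5000 and 10000 IU, with 451 and 629 at an unadjusted p under 0.05 (299 and 568 with library set terms), and 0 (303 and 479) with the libraries of an animal taken as independent. Neither edgeR nor DESeq2 was run for this difference.

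Jejunum and colon of the control animals (10 libraries each) were compared as a reference for the size of differences these libraries show. Absorptive genes marked the jejunum. FABP2, the intestinal fatty acid binding protein (ENSSSCG00000037272, chromosome 8, 104464342 to 104468059), had 8517 ± 8682 CPM in jejunum against 26.7 ± 24.4 in colon, a log2 difference of 8.10 (adjusted p = 1.4e-08). The chemokine CCL25, which draws T cells to the small intestine, had 407 ± 181 against 1.76 ± 1.16 CPM, and the retinol carrier RBP2 841 ± 451 against 4.72 ± 3.496. Enterocyte genes such as SLC5A12, MGAM, ENPEP, SLC15A1 and SLC6A19 were higher in 29 of 33 cases (median 3.06, camera adjusted p = 3.0e-22; adjusted p = 0.088 with an estimated correlation; fry 1.7e-07). The hormones GIP, NTS, CCK and SST were higher by 5.32, 5.43, 4.33 and 2.34 (enteroendocrine list 11 of 17 higher, adjusted p = 0.0024), and the T cell genes CD3E and CD27 by 1.39 and 2.05 (list 28 of 32 higher, median 0.78, adjusted p = 3.8e-06). CD27 no longer passed, at 0.51, in a fit of all 3 diets with dose and library set as terms. With an estimated correlation these lists ended at 0.26 and 0.32.

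Carbonic anhydrase CA1 had 5.01 CPM in jejunum against 2426 ± 1150 in colon, a log2 difference of -9.11 (adjusted p = 5.9e-15). Log2 differences were -6.26 and -5.50 for the posterior patterning genes HOXA10 and HOXA9, -5.78 for TSPAN1 and -3.63 for SELENBP1. Colonocyte genes were lower in 18 of 24 cases (median -1.75, adjusted p = 2.5e-07; adjusted p = 0.088 with an estimated correlation). ADIPOQ, a hormone of fat cells, had 0.477 against 55.9 CPM and FABP4 a log2 difference of -3.15. The adipocyte genes were lower in 13 of 15 cases (median -1.23, adjusted p = 2.7e-07; adjusted p = 0.024 with an estimated correlation). The oxidase DUOX2 and the defensin DEFB1 gave -4.16 and -3.86 (antimicrobial list 13 of 19 lower, adjusted p = 0.0040). Goblet genes were lower in 11 of 16 cases (adjusted p = 0.023), with GALNT12 at -3.65, while TFF2 and MUC13 were higher by 3.92 and 2.78. MUC13 no longer passed, at 0.64, in a fit of all 3 diets with dose and library set as terms. Matrix genes such as FN1 and COL3A1 (22 of 29 lower, adjusted p = 0.0031), smooth muscle markers (22 of 24, adjusted p = 0.0087), cholesterol synthesis genes (18 of 23, adjusted p = 0.018) and respiratory subunits (31 of 36, adjusted p = 0.0016) were lower. NEXN of the muscle list and NDUFA10 of the respiratory list passed here but not in the fit with dose and library set, at -0.34 and -0.23. With an estimated correlation the antimicrobial, goblet, matrix, muscle, cholesterol and respiratory lists ended at 0.27, 0.49, 0.69, 0.71, 0.69 and 0.69. Of 15709 genes tested limma passed 4611, 2325 higher in jejunum and 2286 lower, with 6302 at an unadjusted p under 0.05. The same 10 animals gave both tissues, a pairing this fit left out. With an animal block 5008 genes passed, 4467 of the 4611 among them. All but 1 of the control colon libraries are in sets 2 and 3 and all control jejunum libraries in set 1, so tissue and set overlap here. Of the 4611 genes 2435 passed in the fit of all 3 diets with dose and library set as terms. In that fit the respiratory, muscle and cholesterol lists ended at 0.12, 0.57 and 0.57.

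The genes through which vitamin D acts on calcium uptake were measured in every diet comparison. The receptor VDR (ENSSSCG00000020864, chromosome 5, 78205807 to 78266505) had 127 ± 96.1 normalised reads in jejunum at 5000 IU against 118 ± 56.6 in controls, and 138 ± 100 at 10000 IU against 112 ± 54.2. Its jejunum log2 differences were -0.03 and 0.25, -0.42 and 0.03 with library set as a term, and 0.33 and 0.26 with the position score. In colon it had 177 ± 59.97 against 152 ± 35.1 at 5000 IU, and its log2 differences were 0.18 and 0.32 at 5000 and 10000 IU, and 0.16 and 0.27 between the doses in colon and jejunum. The latter pair became 0.28 and 0.47 with library set as a term, the jejunum value was 0.003 with the position score, and the colon value at 10000 IU was 0.50 without the libraries of set 3. The calcium binding protein S100G (ENSSSCG00000012147, chromosome X, 13107611 to 13114213) had 8534 ± 15885 in jejunum at 5000 IU against 1581 ± 2825, a log2 difference of 0.03 (SE 1.31), and gave -1.71 with library set as a term and 1.18 with the position score. At 10000 IU its log2 difference was 0.67, -0.06 with library set as a term and 0.72 with the position score. Between the doses in jejunum it was 0.64 (SE 1.69), 1.46 with library set as a term and -0.86 with the position score.

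In colon S100G had 2086 ± 2146 against 1149 ± 1003 at 5000 IU, a log2 difference of 0.87 with 8 of 10 libraries above the control median. This was 0.92 with library set as a term and 1.60 without the libraries of set 3. At 10000 IU the difference was -0.36, and -0.21 with library set as a term. Between the doses in colon S100G had 737 ± 429 at 10000 IU against 1950 ± 2029, with a log2 difference of -1.22 (SE 0.47, adjusted p = 0.67). That became -1.04 with library set as a term and -1.86 without the libraries of set 3.

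The apical calcium channel TRPV6 had 17.4 ± 18.1 against 18.96 ± 20.53 in jejunum at 5000 IU and 26.8 ± 34.6 against 18.03 ± 19.5 at 10000 IU. Although its mean was higher at 10000 IU, its log2 differences were -0.14 and -0.31 (SE 0.81 and 0.96), and -0.58 and -0.71 with library set as a term. They were 0.44 and -0.28 with the position score. Between the doses in jejunum TRPV6 differed by -0.18, by 0.11 with library set as a term and by -0.95 with the position score. It was under the filter in colon with means of 9.73 or less, and so was not tested there or for the difference in response. The calcium pump ATP2B1 had 785 ± 340 against 719 ± 229 in jejunum at 5000 IU, a log2 difference of 0.08 that was -0.17 with library set as a term and 0.16 with the position score. It had 996 ± 505 against 685 ± 217 at 10000 IU, 9 of 9 libraries above the control median, a log2 difference of 0.46. In colon its log2 differences were 0.00 and 0.29, and -0.08 and 0.23 with library set as a term. Between the doses they were 0.38 in jejunum (0.21 with the position score) and 0.30 in colon, where 0.14 was left without the libraries of set 3. Across the diet comparisons limma passed none of these genes.

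CYP24A1, the enzyme that degrades active vitamin D, had mean values of 1.02 and 0.163 normalised reads in jejunum at 5000 and 10000 IU and 0.791 and 1.32 in colon. Its control means were 0.427 or less, and a difference was not detectable at this depth. CYP27B1, which makes the active hormone, had means of 1.70 or less in all groups. Neither was tested. Between jejunum and colon of the controls VDR differed by -0.13 (adjusted p = 0.76), S100G by -0.38 (0.73), TRPV6 by 0.87 (0.18) and ATP2B1 by -0.51 (0.070). That fit left out the pairing of tissues by animal, and ATP2B1 passed with an animal block. In the fit of all 3 diets with dose and library set as terms the direction of VDR and S100G turned, to 0.15 and 1.21, and TRPV6 was 1.32 (adjusted p = 0.016). For the difference in response between tissues the values were -0.28 and -0.12 for VDR, -0.95 and 0.79 for S100G, and 0.06 and 0.21 for ATP2B1 at 5000 and 10000 IU. Library set terms made these -0.69 and -0.16, -2.54 and 0.31, and -0.05 and 0.48.

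S100G was low in jejunum libraries with high FABP6. The labels record no sampling position along the jejunum. FABP6, the ileal bile acid binding protein, was at or below 6.46 log2 CPM in 16 jejunum libraries and at or above 11.06 in the other 12. The latter were 2 of 10 control libraries, 5 of 9 at 5000 IU and 5 of 9 at 10000 IU (Fisher's exact test, two-sided, p = 0.17 for each dose against control). S100G ran from 2.68 to 6.81 log2 CPM in those 12 libraries and from 4.86 to 13.52 in the others, where control libraries ran to 11.20, those at 5000 IU from 7.10 to 13.52 and those at 10000 IU from 9.37 to 13.44. The proximal transcription factor GATA4 ran from 0.94 to 5.85 in the 12 libraries and from 4.86 to 6.82 in the others. Control animal 16, with FABP6 at 11.06, had GATA4 at 5.85 and a position score of 3.47, near the control mean of 3.60.

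**Figure D4:**
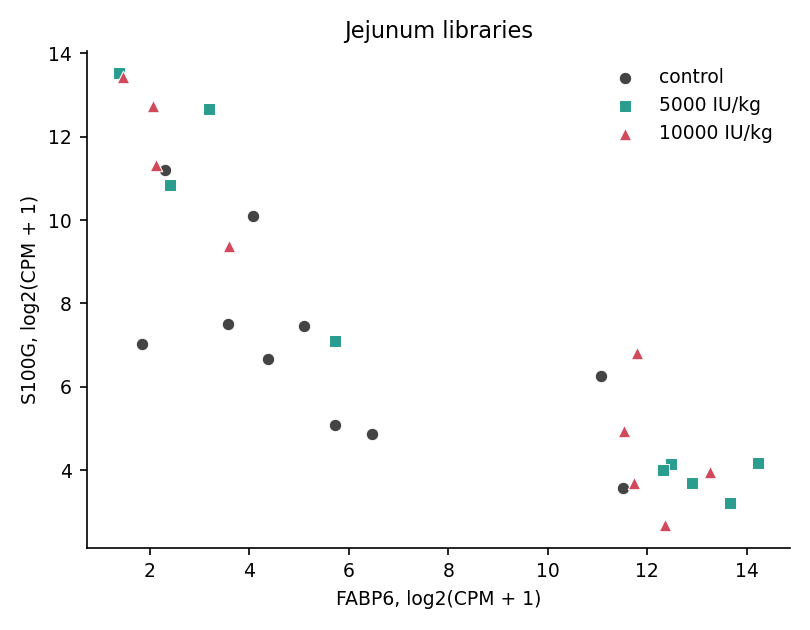
S100G against FABP6 in jejunum libraries, both as log2(CPM + 1), with each point a library coloured by diet. FABP6 leaves a gap between 6.46 and 11.06, and the 12 libraries above it have S100G between 2.68 and 6.81.

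Some gene lists passed in no comparison. Vitamin D metabolism and receptor genes gave camera adjusted p of 0.50, 0.056 and 0.38 in jejunum at 5000 IU, at 10000 IU and between the doses, and 0.93, 0.27 and 0.25 in colon. Their median in jejunum at 10000 IU was 0.25 with 10 of 15 higher. Tight and adherens junction genes gave 0.50, 0.28 and 0.66 in jejunum and 0.71, 0.75 and 0.95 in colon, enteric neuron and glia markers 0.69, 0.33 and 0.17, then 0.37, 0.62 and 0.95, and xenobiotic metabolism genes 0.71, 0.81 and 0.66, then 0.47, 0.34 and 0.95. Between the tissues of the controls these lists gave 0.32, 0.20, 0.20 and 0.47. Vitamin D receptor target genes did pass in jejunum at 10000 IU, at 0.038 as given above. In jejunum at 5000 IU they gave 0.074, with 19 of 28 higher and a median of 0.09.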

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

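The library set tests, the test of dose for the plasma proteins and the position score as a covariate were chosen only after the result was seen. In 299 cases a named gene, or the total reads, was examined within 1 of the 6 groups of 9 or 10 libraries. Of these cases 28 held a library far from the rest of its group by Dixon's ratio, from 14 libraries in all. That ratio is the gap to the nearest library over the range of the group. Chance flags about 1 in 20 independent cases. These cases reuse the same libraries, so the count of 28 cannot be judged against that rate. Values are log2 CPM, with the nearest other library of the group in brackets.

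The jejunum library of control animal 28 was lowest for a run of absorptive and proximal genes. It had CCL25 at 6.03 (8.16), FABP2 at 6.03 (10.78), GIP at 1.20 (4.55), MGAM at 4.44 (8.65), RBP2 at 2.62 (8.61), SLC6A19 at 3.96 (5.4), TFF2 at 2.19 (5.21) and VDR at 2.77 (4.31). Its FABP6 was 11.51, above the gap in that gene, and its position score of -2.68 was the lowest of the jejunum libraries. In other jejunum libraries CD247 was highest in control animal 16 at 7.46 (6.76), RPL7 highest in control animal 17 at 11.39 (10.54), SOCS1 lowest in control animal 23 at 1.94 (2.94) and in animal 12 of the 5000 IU diet at 2.43 (3.68), and XCR1 lowest in animal 8 of the 10000 IU diet at 2.29 (3.10).

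In colon, control animal 17 had the highest ALPL at 5.89 (4.61), HADHB at 7.29 (6.83), PIGR at 12.30 (11.65) and RPL5 at 12.17 (11.40), and the lowest ATP2B1 at 6.70 (7.68). Control animal 16, the single control colon library of set 1, had the highest CTSZ at 7.45 (5.02) and SREBF2 at 8.19 (6.33), and the lowest IFIT1 at 1.51 (2.93). MS4A2 was highest in control animal 23 at 6.74 (5.84) and NEXN lowest in control animal 4 at 6.17 (7.06). At 5000 IU, animal 6 had the highest EREG at 3.73 (3.06) and FCER1A at 4.96 (3.82), and animal 15 the lowest GEM at 1.85 (3.07). At 10000 IU FCER1A was lowest in animal 27 at 1.03 (3.04) and FABP4 lowest in animal 21 at 2.80 (4.34).

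A difference in response between jejunum and colon, tested on the difference within each animal, passed for 8 cases of gene lists. At 5000 IU the medians were 0.33 for interferon genes, 0.94 for bile acid genes and -0.28 for proliferation genes. At 10000 IU they were 0.35 for calcium, phosphate and magnesium transport, 0.21 for interferon genes, -0.60 for myeloid markers, -0.47 for MHC class II genes and 0.42 for smooth muscle markers. None of the 8 passed with a correlation estimated from the data.

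Bile acid genes were higher in jejunum at 5000 IU, and a more distal sampling site in the dosed animals could give this, since FABP6 and SLC10A2 rise toward the ileum. The mean position score was 3.60 in controls and 2.48 at 5000 IU (exact permutation p = 0.37), and with that score as a covariate the list median was 0.88, against 0.70 without it (adjusted p = 0.0055 with an estimated correlation). That argues against position, as this score measures it, as the whole source. Yet FABP6 fell from 3.07 to 1.42, SLC10A2 from 2.72 to 1.79, NR1H4 from 1.38 to 1.09 and SLC51A from 1.21 to 1.15. Of the genes examined singly only SLC51B rose, from 0.61 to 0.84. The score does not follow FABP6 in every library, with a score of 3.47 beside FABP6 at 11.06 in control animal 16. The permutation test does not show that positions were equal. Library set alone as the source is also argued against, by a camera adjusted p of 0.0016 with an estimated correlation when it was a term. The median then fell to 0.48, with 8 of 10 higher. All jejunum controls are in set 1, so that term amounts to leaving out the 2 dosed libraries of set 3. These libraries, of animals 18 and 6, had position scores of 5.44 and 6.66, so the dosed libraries that remain are more distal on average. Set and position were not fitted together for this list, so position and set acting jointly stay open. Dose, fed to the whole animal, may be the source and stays a hypothesis, since positions that the 7 marker genes do not measure are open.

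Transcripts of plasma proteins were higher in the 12 libraries of set 3, in all diets. RNA of liver in these libraries is a candidate source. Between colon libraries of sets 3 and 2, 17 hepatocyte enzymes and receptors gave a median log2 difference of 2.14, and 13 of them did not overlap. These proteins are not secreted. The 17 plasma proteins gave 2.88, and 17 of 17 did not overlap, but their mean defines set 3, so these values are built in. ALB was read in every library, at 148 CPM or more, so a low level is not particular to set 3. Whether dose plays a part cannot be told apart from chance, with 9 of 38 dosed and 3 of 20 control libraries in the set (Fisher's exact test, two-sided, p = 0.51). That test takes libraries as independent and pools the tissues, though 28 animals gave both. In colon the set held 3 libraries of each diet. In jejunum it held 0 of the controls, 2 at 5000 IU and 1 at 10000 IU. Carry-over between libraries at preparation or on the sequencer, and handling of tissue, were not tested.

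OASL and other interferon genes were higher in jejunum at 5000 IU, but limma did not pass OASL (adjusted p = 0.20). With an estimated correlation the camera adjusted p of the list was 0.17. It was 0.11 with library set as a term and 0.099 with the position score. Library set could not be the whole source, since OASL differed by 2.81 (95% interval 1.55 to 4.06) among the 17 libraries of set 1. Position is argued against by a difference of 3.03 (1.88 to 4.18) with the position score as a covariate, beside 2.95 (1.83 to 4.07) without it. A viral infection shared by pen mates, or a response to the dose, may be the source, and the labels give no pen or health record to test the former.

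Other splits of the same libraries were drawn 100 times for each comparison, the real split included. For the diet comparisons and the differences in response, the real limma count was 0. All 100 splits gave as many, which any split must, so these counts say nothing about chance. The highest count among the other splits was 1, 40 and 15 in jejunum at 5000 IU, at 10000 IU and between the doses, 120, 62 and 1 in colon, and 1705 and 1 for the responses at 5000 and 10000 IU. For the 1341 genes at an unadjusted p under 0.05 in colon at 10000 IU, 10 of 100 splits gave as many (highest other 2475), and for the 1000 between the doses in colon 23 of 100 did (highest other 2270), so chance cannot be excluded there. With library set as a term these numbers were 809 and 665, where 666 and 669 were due by chance. Library set, unequal between these groups, is thus another candidate source of the excess. Splits that follow the library sets called 669 to 3883 genes, but the sets were made from values of the same libraries, so this is in part built in.

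List means were tested in the same way for 3 lists picked after their list tests were seen. For bile acid genes in jejunum at 5000 IU the real mean of 1.06 was matched by 1 of 100 splits, the real one (next -1.04). For interferon genes the mean of 0.595 was matched in size by 2 of 100 (highest other -0.685), and for proliferation genes in colon at 5000 IU the mean of 0.55 by 2 of 100 (highest other 0.56). The lists were picked because their tests were extreme, so these counts repeat that choice. Adjusted over the lists and with an estimated correlation, camera p was 0.0012 for bile acid, 0.17 for interferon and 0.18 for proliferation genes. Chance cannot be excluded for the latter pair. For bile acid genes the value rests on an estimated correlation of 0.0031. At 10000 IU in jejunum that correlation was 0.088 and the camera adjusted p 0.18. Another split came to -1.04, so chance is not excluded for bile acid genes either. Between jejunum and colon of the controls the 4611 genes were reached by 1 of 100 splits, the real one (highest other 1). Among splits that part every pair it was also 1 of 100 (highest other 3939). No other drawn split reached as many, and 1 of 100 is the smallest share this test can give. Tissue and library set overlap in these animals, so the splits cannot tell them apart.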

How the results depend on the processing

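In all 2637 values were computed under alternative settings. The settings with library sets, the position score and all 3 diets in the tissue fit were chosen after seeing the data. Of the alternative counts of genes 108 stayed within 1.5 times the reported count and 8 did not. A count of 0 beside a reported 0 was taken as staying, and only the tissues of the controls had a reported count over 0. Most of the 108 thus say no more than that no gene passed. Named genes kept their direction and side of the threshold in 1998 cases, 15 passed where they had not, 4 no longer passed and 36 changed sign. In the diet comparisons and the differences in response no gene had passed, so a kept side there means that the gene stayed uncalled. Of 85 list calls 2 held with an estimated correlation, 11 with fry, 75 without the filter and 68 with library set as a term. In simulated data of these depths limma found 81.5 to 96.8% of genes changed 4 fold in the diet comparisons, 19.7 to 42.4% at 2 fold and 1.5 to 4.5% at 1.5 fold. For the differences in response it found 60.7 and 61.9% at 4 fold, 4.6 and 6.2% at 2 fold and 0 and 1.5% at 1.5 fold, so small changes are beyond the depth and spread of these groups. Apart from the following, the cause was not tested for any value below. Set 3 alone leaves 3 libraries against 3. In jejunum at 5000 IU DESeq2 on the recovered reads and the authors' table both had 1218 genes at an unadjusted p under 0.05. Their adjustments ran over 28230 and 14197 genes. The correlation preset at 0.01 was there estimated at 0.38 for interferon, 0.75 for smooth muscle and 0.0031 for bile acid genes.

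DESeq2 on the recovered reads passed 4 genes in jejunum at 5000 IU, 1 at 10000 IU and 2 in colon at 5000 IU, and the authors' values gave 7, 1 and 2, where limma passed 0. Between the doses in colon, set 3 alone passed 1. The number of genes at an unadjusted p under 0.05 moved more than the calls. With array weights it was 1123 in jejunum at 10000 IU (reported 664) and 856 between the doses (reported 295), and without the smallest library of each group 923 in jejunum at 5000 IU (reported 511). Between tissues, all 3 diets in a fit with a dose term passed 7724, where the reported count was 4611. DESeq2 and the authors' table brought OASL, LYPD8 and MEP1B past the threshold, and the latter TAP1, OAS2 and KRT7. Between tissues TRPV6 passed in the fits of all 3 diets with dose (1.05) and with dose and library set (1.32), and ATP2B1 with an animal block (-0.51) and in the fit with dose (-0.41). With dose and library set as terms MUC13 (0.64), CD27 (0.51), NEXN (-0.34) and NDUFA10 (-0.23) no longer passed between tissues.

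Changes of sign were among genes whose reported difference was small beside its error. With edgeR VDR in jejunum at 5000 IU was 0.10 (reported -0.03), TRPV6 at 10000 IU 0.56 (reported -0.31) and between the doses 0.68 (reported -0.18), and ATP2B1 in colon at 5000 IU -0.030 (reported 0.00). With DESeq2, and in the authors' table, these were 0.11, 0.57, 0.69 and -0.026. With array weights VDR in jejunum at 5000 IU was 0.049, S100G at 10000 IU -0.23 (reported 0.67) and between the doses -0.36 (reported 0.64), and ATP2B1 in colon at 5000 IU -0.094. With a smooth muscle score as covariate VDR at 5000 IU was 0.065, and TRPV6 0.032 at 5000 IU (reported -0.14), 0.047 at 10000 IU and 0.034 between the doses. With the position score VDR at 5000 IU was 0.33, TRPV6 0.44, and S100G between the doses -0.86. TRPV6 between the doses was 0.084 with a pseudocount of 5, 0.030 with all 3 diets in a fit and 0.11 with library set as a term. With library set as a term, and without the libraries of set 3, S100G in jejunum was -1.71 at 5000 IU (reported 0.03) and -0.059 at 10000 IU, and ATP2B1 at 5000 IU -0.17 (reported 0.08). With library set as a term ATP2B1 was -0.083 in colon at 5000 IU and -0.047 for the 5000 IU response (reported 0.06). With dose and library set as terms VDR between tissues was 0.15 (reported -0.13) and S100G 1.21 (reported -0.38).

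The number of the 9 comparisons in which a list passed also moved. With an estimated correlation it was 0 for calcium, phosphate and magnesium transport, vitamin D receptor targets, goblet, antimicrobial, interferon, inflammatory, T and NK cell, B cell, myeloid, mast cell, MHC class II, smooth muscle, matrix, endothelial, erythroid, enterocyte, colonocyte, proliferation, enteroendocrine, cholesterol, fatty acid oxidation, immediate early, unfolded protein, mitochondrially encoded, respiratory and ribosomal lists, and 1 for adipocyte (reported 2) and bile acid genes (reported 3). With fry it was 0 for interferon, inflammatory, B cell, myeloid, mast cell, MHC class II, smooth muscle, endothelial, proliferation, immediate early, unfolded protein, mitochondrially encoded and ribosomal lists. It was 1 with fry for vitamin D metabolism and enteric neuron and glia (reported 0 for both), calcium, goblet, antimicrobial, T and NK cell, matrix, adipocyte, bile acid, enteroendocrine, cholesterol, fatty acid oxidation and respiratory lists. Without the filter it was 0 for receptor targets and erythroid markers and 1 for mitochondrially encoded transcripts (reported 3). With library set as a term it was 1 for calcium transport (reported 2), 0 for receptor targets (reported 1), 5 for T and NK cell (reported 3), 1 for adipocyte (reported 2), 3 for colonocyte (reported 1), 0 for unfolded protein (reported 1) and 3 for respiratory lists (reported 5).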

Other observations

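The tests of S100G and CLDN2 with the position score and the values with library set as a term were chosen only after the result was seen. CLDN2, which lets calcium and water pass between epithelial cells and is a known target of the vitamin D receptor, was higher in jejunum at both doses. It had 185 ± 105 normalised reads at 5000 IU (n = 9) against 76.8 ± 24.6 in controls (n = 10), with 8 of 9 libraries above the control median, beside the values at 10000 IU given above. It was chosen at 5000 IU after its values were seen, and passed when adjusted over the list alone in the calcium transport and receptor target lists there. With the position score as a covariate its log2 differences were 1.18 (95% interval 0.56 to 1.81) at 5000 IU and 1.11 (0.61 to 1.61) at 10000 IU, and with library set as a term 0.97 and 0.94. Its limma adjusted p over all genes were 0.997 and 0.88, and the same control animals serve in both comparisons.

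In colon at 10000 IU, genes chosen after their values were seen passed when adjusted over their list alone. ADIPOQ, a hormone of fat cells, had 130 ± 57.0 against 259 ± 122 and the fatty acid carrier FABP4 165 ± 82.5 against 368 ± 176, and 0 of 10 dosed libraries were above the control median for either (log2 differences -0.99 and -1.23, and -0.998 and -1.04 with library set as a term). FASN, which makes fatty acids and is in the same list, was higher, with 993 ± 309 against 608 ± 183, a log2 difference of 0.70 and 0.73 with library set as a term. That list of adipocyte genes did not pass, with 7 of 15 higher, 8 lower and a median of -0.07 (camera adjusted p = 0.14). The sodium and proton exchanger SLC9A2 had 170 ± 113 against 51.9 ± 52.5, with 10 of 10 above the control median (1.82, and 1.43 with library set as a term). PDIA3, a chaperone that also binds vitamin D at the membrane, had 1245 ± 548 against 501 ± 298, with a log2 difference of 1.34 that was 0.54 with library set as a term.

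S100G, the calcium carrier that active vitamin D induces, may be higher at a given position score in jejunum of dosed animals. With the position score as a covariate its log2 difference was 1.18 (95% interval -0.44 to 2.81) at 5000 IU and 0.72 (-0.87 to 2.31) at 10000 IU, and -0.06 and 0.28 with library set added to the score. These intervals include 0, so an effect of dose on S100G cannot be told apart from none. As a separate limit, the jejunum libraries of set 3 are all from dosed animals and hold some of the highest S100G values.

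Pairs of jejunum and colon libraries from 1 animal were weakly alike. After removing group and library set effects within each tissue, the median correlation across genes was 0.13 within an animal and -0.005 between animals. Of the jejunum libraries 6 of 28 were closest to the colon library of their own animal. Over the 500 genes of largest variance the median was 0.285, and 11 of 28 were closest. No libraries were duplicates, with a highest correlation of 0.966 in both tissues.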
